A study of Zea mays with 10 samples.

How the data were processed

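Transcript levels were measured along the third leaf of maize (Zea mays, inbred line B73) grown in a greenhouse with 16 h of light. Per the labels, the leaf measured 18 cm from its tip to where it emerged, on plants of 14 to 15 days, and was cut into 10 slices of 2 cm, the last of them from the part not yet emerged. Slice 1 was the tip and the oldest tissue, and slice 10 was the base, the youngest tissue, still inside the sheath. Each replicate was a pool of 20 plants, and each slice had 4 arrays, 40 in all. The arrays were custom Agilent oligonucleotide arrays of 43197 spots, read in a single colour.

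The authors extracted the scans with Agilent Feature Extraction 9.5.3.1, and per the file headers each spot's processed signal is an intensity in arbitrary scanner units, corrected for background and detrended, with no scaling between arrays. The deposited table of values is on the log2 scale, with a column per slice. Compared with the scanner files, each of its columns matched the slice's mean log2 signal with the column median and each probe's mean removed. It carries no replicates, so all tests started from the scanner files.

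The 1417 control spots were left out, which left 41780 probes. Signals were taken as log2, and each array's 75th percentile was subtracted. Spots marked as non-uniform or as population outliers by the scanner software were set to missing (829 over all arrays). Each probe had a single spot per array. The 31830 probes well above background on all 4 arrays of at least 1 slice were tested. The count of arrays limits the precision of each value. Between 25019 and 34188 probes per array were well above background, the 75th percentile signal ran from 347 to 1097, and 7 spots were saturated over all arrays. Probe names came from the platform table and from a table of RefSeq genes, in which 3205 probes had a symbol, out of 6203 with a RefSeq accession. Of the tested probes, 9990 had a name or description, and the 31830 probes stood for 26469 genes by their best database hit. Probe identifiers are given as the platform table has them, without genome positions.

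Slices were compared with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) and with plots in Python 3.11.15 and matplotlib 3.10.9. A linear model with slice as a factor was fitted to all 40 arrays, and moderated tests were two-sided with Benjamini-Hochberg adjusted p under 0.05. The comparisons were all 10 slices (moderated F test), slice 10 against 1, 10 against 5, 5 against 1, the 9 neighbouring pairs, and the difference between the basal change (10 minus 5) and the distal change (5 minus 1). Gene lists were tested with limma's camera, 1 probe per gene, a preset correlation of 0.01, at least 5 measured genes and adjustment over the 27 lists tested in a comparison. Comparisons, lists and the rule for naming genes were set before the data were examined, and the lists were matched to symbols, identifiers or descriptions. A match inside a word had at first brought unrelated genes into some lists, so the matching was restricted to the starts of words after the data were seen. Random lists matched to each list on mean signal over all arrays were also added after the data were seen.

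Genes were named by rule. For slice 10 against 1, the 8 largest rises and 8 largest falls were taken, for 10 against 5, 5 against 1 and 10 against 9 the 5 largest of each, and for other neighbouring pairs the 2 largest of each. These had a name, signals well above background on all 8 arrays and no overlap between the 2 slices' arrays. From each list, the members with the largest called differences in slice 10 against 1 were added, up to 4, or up to 6 for the lists of the C4 cycle, the Calvin cycle, sucrose, nitrogen and the cell cycle, with at least 1 of each direction where both occurred. This gave 195 differences of 166 genes, and in all 195 of them the 4 arrays of each slice lay on opposite sides without overlap. Where no array of a slice was well above background, a lower bound on the fold was computed against the larger of the array's dimmest signal still well above background and the spot's own signal, averaged over the slice's arrays. Such a bound, given as "at least", holds only for the background correction used. With normexp, some of these genes had differences smaller than their bound.

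All 4 arrays of a slice shared a slide, so slide and slice cannot be told apart. Slices 1 and 2 were scanned on the first day, 3 to 6 on a second and 7 to 10 on the last. A scan-day block could not be fitted to slices of different days. It leaves differences within a day as they were, so slices 10 against 7, 6 against 3 and 5 against 3 were added as comparisons within a day. A model with scan day as a term and slice number as a linear covariate was fitted as well. It gives the slope per slice within scan days, multiplied by the distance in slices, and not the difference of the 2 slices themselves. Other alternatives were normexp background correction (offset 50), quantile normalization, scaling to the array median or to the 75th percentile of probes above background on all arrays, no filter or a stricter one on dim probes, limma's array weights, 1 probe per gene, a minimum log2 difference of 1, fits to the compared slices alone, a replicate block, camera with an estimated correlation, and leaving out each array. Scaling to spike-in transcripts, normexp with local backgrounds above 2 times the array's median set to that median, the linear scan-day model and the first matching of lists were chosen after the data were seen.

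The procedure was tested on simulated data with the same layout, in which log2 changes were planted in slice 10. For slice 10 against 1, it called 40% of the changes of 0.5, 76.4% of those of 1 and 91.4% of those of 2, all with the right sign, and 7 unchanged probes. A simulated list of 40 shifted genes was called (adjusted p = 1.21e-41), and a list of 40 unshifted genes was not (adjusted p = 0.836). The simulated noise was independent between genes, all probes counted as above background, and no slide or scan-day effect was added. The simulation therefore does not test camera on correlated genes, and the correlation estimated for the cytosolic ribosomal list was 0.307.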

Results

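The 40 arrays held 4 replicates of each of 10 slices from the tip (slice 1) to the base (slice 10) of the growing maize leaf. The 75th percentile signal, before scaling, was highest in slice 10 with a mean of 988 (SD 157, n = 4) and lowest in slice 3 with 372 (SD 35.5, n = 4). The mean number of probes well above background was highest in slice 1 with 32628 (SD 1445, n = 4) and lowest in slice 7 with 27098 (SD 2439, n = 4). Values below are differences of log2 signal after scaling, with 4 arrays per slice and, for some, the standard error (SE). In each of the 195 differences named by rule, the arrays of the 2 slices did not overlap. The rule required this of the largest rises and falls.

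The series follows transcript levels from young to old leaf tissue. More transcripts were highest in each end slice than in any other single slice. Of 29125 probes that differed among the 10 slices, 6466 had their highest mean in slice 10 and 5204 in slice 1, against 1409 in slice 4. Pyruvate,orthophosphate dikinase (OptiV1C17314), which regenerates the carbon acceptor of C4 photosynthesis, had a mean of 3.98 in slice 4 (SD 0.15, n = 4) and of -1.61 in slice 9 (SD 0.64, n = 4). Cellulose synthase 11 (OptiV1C11370), named among the enzymes of secondary walls, had a mean of -4.61 in slice 1 (SD 0.231, n = 4) and of 4 in slice 10 (SD 0.325, n = 4). The 29125 probes were 91.5% of the 31830 tested (moderated F test, adjusted p under 0.05). The first 2 principal components held 60.8% and 13.5% of the variance between arrays.

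**Figure D1:**
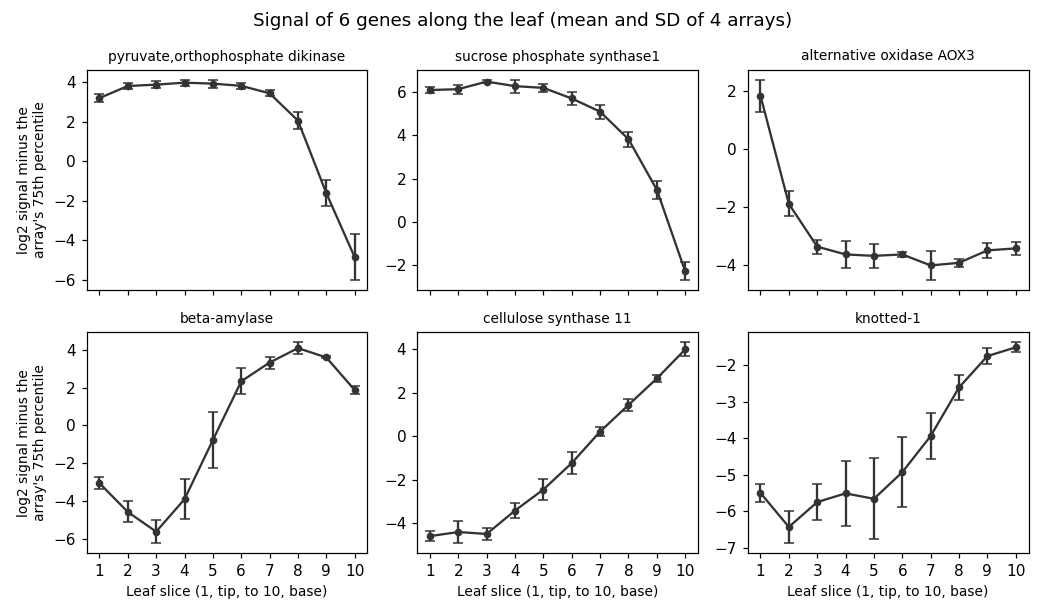
Signal of 6 genes by leaf slice, as log2 signal minus the array's 75th percentile. Points are means and bars are SD of 4 arrays per slice. The dikinase and sucrose phosphate synthase1 were lowest in slice 10, the alternative oxidase was highest in slice 1 with 1.84, the beta-amylase in slice 8 with 4.08, and cellulose synthase 11 and knotted-1 in slice 10.

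Slice 10 against slice 1 compared the youngest with the oldest tissue. Among the largest differences, lipid binding proteins and a wall protein were far higher at the base, and sucrose phosphate synthase1 and 3 peptide transporters far higher at the tip. A lipid binding protein (OptiV1S31825) was 1870-fold higher at the base (log2 difference 10.9, SE 0.365), and others of that description were 1490-fold (OptiV1S19459) and 665-fold higher (OptiV1C04978). Rapid alkalinization factor 1 (OptiV1S30507), a secreted signalling peptide, was 717-fold higher (log2 difference 9.49, SE 0.258), and vegetative cell wall protein gp1 (OptiV1S20294) 615-fold. An ATP-driven membrane transporter (OptiV1C11461), L-ascorbate oxidase (OptiV1C02069) and a protease inhibitor and lipid transfer family protein (OptiV1C03933) were 600-fold, 552-fold and 541-fold higher. Sucrose phosphate synthase1 (OptiV1C10670), an enzyme of sucrose synthesis, was 333-fold lower at the base (log2 difference -8.38, SE 0.203). Probes for 3 transcripts described as peptide transporter PTR2 (OptiV1C08933, OptiV1S18541, OptiV1S22702) were 425-fold, 415-fold and 152-fold lower. Bundle sheath cell specific protein 1 (OptiV1C04996) was 246-fold lower, viviparous-14 (OptiV1C05368), an enzyme of abscisic acid synthesis, 213-fold, a mixed-linkage glucanase (OptiV1C14456) 118-fold and flowering promoting factor-like 1 (OptiV1C06890) 108-fold.

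In all, 23168 probes differed between slices 10 and 1, with 10071 higher and 13097 lower at the base (adjusted p under 0.05). The adjusted p of these 16 genes ran from 2.19e-30 (OptiV1S19459) to 1.77e-16 (OptiV1S20294). The 2 slices were scanned on different days. Within the last day, 21374 probes differed between slices 10 and 7 (9281 higher, 12093 lower), and 116 of the 133 genes named for slice 10 against 1 differed the same way there, 6 the opposite way. With scan day as a term, 15070 probes had a linear trend over slices 1 to 10. Among them, 14233 were in the 23168 with the same sign. By that trend, 124 of the 133 named genes passed with the same sign. Scaled to spike-in transcripts, the median of all probes was 0.778 in place of -0.175, and 18373 probes were higher at the base and 3720 lower. With scaling to the array median it was -0.334.

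Genes of protein synthesis were higher at the base. Of 110 cytosolic ribosomal protein genes, 99 rose and 4 fell from slice 1 to slice 10 over all probes tested, the same counts as when adjusted over the list alone, with a median of 1.14 on the log2 scale (adjusted p = 1.19e-14; adjusted p = 0.244 with an estimated correlation). The 60S protein L18A (OptiV1C07865) rose 10.8-fold and the 40S protein S9 (OptiV1S33052) 3.8-fold. The 4 that fell, 3 of them named after their values were seen, were the 40S protein S27a (OptiV1S20128, log2 difference -3.12 with 1 array of slice 10 above background) and the 60S proteins L33-B (OptiV1C11634, -0.35), P2A (OptiV1C05265, -0.82) and L24 (OptiV1C01911, -0.46). The 40S protein S24 (OptiV1C04649) had a log2 difference of 2.38 with 1 array of slice 1 above background, and of -0.03 with normexp background correction. Of 42 plastid ribosomal protein genes, 30 rose and 1 fell, also when adjusted over the list alone, with a median of 1.34 (adjusted p = 1.49e-07; adjusted p = 0.0692 with an estimated correlation). The 30S protein S9 (OptiV1C06723) rose 8.19-fold, 2 probes for the 50S protein L18 (OptiV1S23113, OptiV1S24398) 7.34-fold and 7.31-fold, and the 30S protein S17 (OptiV1C08543) fell by 0.61 on the log2 scale but had 0.34 when scaled to spike-in transcripts.

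Genes of cell walls and of the cuticle were higher at the base as well. Of 48 genes of wall expansion, 32 rose and 5 fell (33 and 5 adjusted over the list alone), with a median of 1.46 (adjusted p = 2.22e-05; adjusted p = 0.143 with an estimated correlation). Beta-expansin 4 (OptiV1C12944), a wall-loosening protein, had a log2 difference of 9.68 with 1 array of slice 1 above background. Fasciclin-like arabinogalactan protein 8 (OptiV1S31128), which is also on the secondary wall list, rose 170-fold, a xyloglucan endotransglucosylase (OptiV1C11915) 133-fold, and an arabinogalactan protein (OptiV1C13799) fell 2.34-fold. Of 35 genes of secondary walls and lignin, 24 rose and 7 fell, also when adjusted over the list alone, with a median of 1.34 (adjusted p = 6.47e-05; adjusted p = 0.0692 with an estimated correlation). Cellulose synthase 11 (OptiV1C11370) rose 389-fold and cellulose synthase10 (OptiV1C06892) 122-fold. A cinnamoyl CoA reductase-like gene (OptiV1C04740) was at least 3.99-fold lower at the base. Of 14 cuticle and wax genes, 10 rose and 3 fell, also when adjusted over the list alone, with a median of 0.93 (adjusted p = 0.0291; adjusted p = 0.247 with an estimated correlation). The cuticle call was also lost with normexp (median 0.40, adjusted p = 0.0538, or 0.45 and 0.0572 with bright backgrounds set to the median) and with spike-in scaling (median 1.88, adjusted p = 0.123). The very-long-chain fatty acid condensing enzyme CUT1 (OptiV1S21213) rose 66.2-fold, a nonspecific lipid-transfer protein (OptiV1C04375) 32.4-fold and glossy1 (OptiV1C10689) 7.9-fold, while a 3-ketoacyl-CoA synthase (OptiV1C15488) fell 19.4-fold.

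Among genes of photosynthesis, the lists moved in different directions between slices 1 and 10. Of 12 Calvin cycle genes, 8 fell and 0 rose, also when adjusted over the list alone, with a median of -0.83, or 0.13 when scaled to spike-in transcripts (adjusted p = 0.0423; adjusted p = 0.313 with an estimated correlation). That call was also lost with quantile normalization (median -0.62, adjusted p = 0.0809) and spike-in scaling (adjusted p = 0.11). The same held with normexp (median -0.77, adjusted p = 0.199, or -0.81 and 0.0913 with bright backgrounds set to the median). Of 1000 random lists of genes with the same brightness, 50 had a median as low, and the median of those lists was -0.38. Phosphoribulokinase (OptiV1S21029, OptiV1S23973) fell 4.24-fold and 4.02-fold and RUBISCO activase1 (OptiV1C09123) 3.48-fold. The B subunit of glyceraldehyde-3-phosphate dehydrogenase (OptiV1C15750) fell 2.86-fold. Glyceraldehyde-3-phosphate dehydrogenase1 (OptiV1S34459) and ribose-5-phosphate isomerase (OptiV1C10655) fell by 0.93 and 0.88 on the log2 scale, and had 0.03 and 0.08 when scaled to spike-in transcripts. Of 8 chlorophyll synthesis genes, 6 rose and 1 fell, also when adjusted over the list alone, with a median of 1.43 (adjusted p = 0.0461; adjusted p = 0.247 with an estimated correlation). That call was lost with scan day as a term (adjusted p = 0.645), with spike-in scaling (adjusted p = 0.123) and without slice 7 replicate 2 (adjusted p = 0.0507). The methyltransferase of magnesium-protoporphyrin IX (OptiV1S31787) rose 3.59-fold, coproporphyrinogen III oxidase (OptiV1C15980) 3.49-fold and magnesium chelatase (OptiV1C13645) 2.98-fold. The list also held siroheme uroporphyrinogen methyltransferase1 (OptiV1C17652), which is not an enzyme of chlorophyll synthesis (log2 difference -0.37, adjusted p = 0.222). Chlorophyllide a oxygenase (OptiV1C13335) fell by 0.83 on the log2 scale, and had 0.13 when scaled to spike-in transcripts. In slice 10 against 7, both of the same scan day, the methyltransferase (log2 difference -0.17) and the chelatase (-0.46) were lower.

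For 52 genes of photosystems and light harvesting, 6 rose and 30 fell, also when adjusted over the list alone, and the list did not pass (median -0.41, or 0.54 when scaled to spike-in transcripts, adjusted p = 0.0574). It passed with scaling to the array median (median -0.57, adjusted p = 0.0439). It also passed with scan day as a term (median -1.61, adjusted p = 3.28e-06). That value comes from a straight line along the leaf, while the list's median profile was -0.58 in slice 1, 0.38 in slice 7 and -0.94 in slice 10. Photosystem II protein D1 (psbA, OptiV1C16130) fell 10.5-fold, a chlorophyll a/b-binding protein (OptiV1C13482) 6.35-fold and photosystem II protein D2 (OptiV1S17999) 3.84-fold, while oxygen-evolving enhancer protein 3 (OptiV1S21007) rose 2.12-fold. For 17 C4 cycle genes, 6 rose and 9 fell, also when adjusted over the list alone, and the list did not pass (median -0.70, or 0.25 when scaled to spike-in transcripts, adjusted p = 0.24). The dikinase (OptiV1C17314) had a log2 difference of -8.05 with 3 arrays of slice 10 above background, and a carbonic anhydrase (OptiV1C09393) 4.36-fold. Another (OptiV1C00084) was at least 1.91-fold lower, and a further one (OptiV1C01051) at least 6.84-fold higher. The list also held genes outside the C4 cycle: a housekeeping phosphoenolpyruvate carboxylase (OptiV1C10576, log2 difference 2.18 with 2 arrays of slice 1 above background) and a non-photosynthetic NADP-malic enzyme (OptiV1C09071), which fell 4.46-fold.

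Genes of sugar and starch metabolism moved both ways. For 8 genes of sucrose synthesis and export, 1 rose and 5 fell (median -0.95, or 0.0045 when scaled to spike-in transcripts, adjusted p = 0.225): sucrose transporter1 (OptiV1C00669) fell 5.22-fold, sucrose phosphate synthase III (OptiV1S19316) 3.38-fold and a further such synthase (OptiV1C14880) 2.69-fold. Sucrose transporter 2 (OptiV1S28476) rose 1.51-fold, and the cytosolic fructose-1,6-bisphosphatase (OptiV1C00797) fell by 0.47 on the log2 scale but had 0.49 when scaled to spike-in transcripts. For 30 genes of starch synthesis and breakdown, 7 rose and 19 fell (median -0.80, or 0.16 when scaled to spike-in transcripts, adjusted p = 0.0518). This list passed with normexp, with quantile normalization, with scaling to or testing of probes above background on all arrays, and with spike-in scaling (adjusted p from 0.0106 to 0.0492). The large subunit of glucose-1-phosphate adenylyltransferase (OptiV1C14932) fell 11.1-fold, a beta-amylase (OptiV1C10255) 10.1-fold and shrunken-2 (OptiV1S28850) 8.56-fold, while another beta-amylase (OptiV1C02764) rose 30.1-fold. For 10 genes of sucrose cleavage, 4 rose and 4 fell (adjusted p = 0.872). An insoluble beta-fructofuranosidase (OptiV1C10247) was at least 44.2-fold higher, a sucrose synthase (OptiV1C11401) had a log2 difference of 6.07 with 1 array of slice 1 above background, sucrose synthase2 (OptiV1C15484) fell 6.17-fold and a neutral invertase (OptiV1C03202) 3.73-fold. A member described as an invertase or pectinesterase inhibitor (OptiV1S22167, log2 difference 0.56) does not cleave sucrose. For 5 photorespiration genes, 1 rose and 4 fell (median -0.61, or 0.34 when scaled to spike-in transcripts, adjusted p = 0.462). A serine hydroxymethyltransferase (OptiV1C03901) rose 4.43-fold and another (OptiV1C09175) fell 2.77-fold. A glycine decarboxylase subunit (OptiV1S31744) had a log2 difference of -1.96 with 2 arrays of slice 10 above background. An aminomethyltransferase (OptiV1C16983) fell by 0.61 on the log2 scale but had 0.34 when scaled to spike-in transcripts. The counts of these 4 lists were the same when adjusted over the list alone.

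Regulators of growth and hormone genes also moved both ways. For 27 genes of leaf growth and patterning, 15 rose and 5 fell (adjusted p = 0.0799). Rough sheath2 (OptiV1C00118), a regulator of knotted-class genes, rose 85.5-fold. Liguleless4 (OptiV1C15422) and knotted-1 (OptiV1C06099), homeobox genes of the shoot, had log2 differences of 4.58 and 3.99 with 1 and 3 arrays of slice 1 above background. A TCP transcription factor (OptiV1C11008) fell 44.1-fold. For 83 auxin genes, 38 rose and 25 fell (adjusted p = 0.0799). Genes described as SAUR52 (OptiV1C01965, OptiV1C07913) rose 65.8-fold and 26.8-fold, an auxin efflux carrier (OptiV1C13860) rose 24-fold and IAA23 (OptiV1S29473) fell 13-fold. For 41 gibberellin genes, 19 rose and 13 fell (adjusted p = 0.254). Anther ear1 (an1, OptiV1C06635), ent-kaurene oxidase (OptiV1C17046), both of gibberellin synthesis, and a gibberellin 2-beta-dioxygenase (OptiV1C00971) rose 34.9-fold, 24.8-fold and 30.6-fold, and a receptor (OptiV1S29383) fell 12.2-fold. For 32 cytokinin genes, 11 rose and 15 fell (median -0.15, or 0.80 when scaled to spike-in transcripts, adjusted p = 0.343). Cytokinin dehydrogenase 10 (OptiV1C10908) fell 76-fold, a cytokinin glucosyltransferase (OptiV1S30934) 41.1-fold, another (OptiV1C09217) was at least 26.5-fold lower, and a further one (OptiV1S31770) rose 3.4-fold. The counts of these 4 lists were the same when adjusted over the list alone.

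The circadian clock list passed with lower levels at the base. Of its 10 genes, 8 fell and 0 rose, also when adjusted over the list alone, with a median of -1.53 (adjusted p = 0.0291; adjusted p = 0.143 with an estimated correlation), and the call was lost with normexp and bright backgrounds set to the median (adjusted p = 0.0572). Gigantea 1B (OptiV1C00225) fell 6.15-fold, LHY (OptiV1C10326) 5.58-fold, pseudo-response regulator 37 (OptiV1S18321) 4.72-fold and gigantea 1A (OptiV1C11836) 4.13-fold.

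The other lists did not pass in slice 10 against 1. For 28 core histones, 16 rose and 6 fell (adjusted p = 0.119), with histone H2A variant 1 (OptiV1S24596) 18.2-fold and a histone H2A (OptiV1S25360) 5.58-fold higher and 2 histone H1 genes (OptiV1S29237, OptiV1C00759) 6.94-fold and 5.11-fold lower. For 25 genes of the cell cycle and DNA replication, 7 rose and 7 fell (adjusted p = 0.49). A minichromosome maintenance protein (OptiV1C14409) rose 7.23-fold, replication origin activator 2 (OptiV1S33750) had a log2 difference of 2.74 with 3 arrays of slice 1 above background, MAD2 (OptiV1C10408) and MCM10 (OptiV1C16506) rose 3.07-fold and 2.6-fold, and cyclin1 (OptiV1C05468) was at least 2.03-fold lower. The member of that list with the largest difference was CUT1 (OptiV1S21213), an enzyme of fatty acid elongation. For 45 genes of senescence and autophagy, 13 rose and 18 fell (adjusted p = 0.808). Its largest rises were 2 xylem cysteine proteinases (OptiV1S22576, 296-fold, and OptiV1S33418, a log2 difference of 8.88 with 3 arrays of slice 1 above background), which act in xylem cells. A leaf senescence protein-like gene (OptiV1S29106) rose 232-fold, and a legumain (OptiV1C12780) fell 7.26-fold. For 14 genes of nitrogen assimilation, 5 rose and 6 fell (adjusted p = 0.956). Asparagine synthetase 2 (OptiV1C06380) and a clone like NADH-dependent glutamate synthase (OptiV1N37559) were at least 15.7-fold and 6.49-fold higher. Nitrate reductase (OptiV1C08466), nitrite reductase (OptiV1C09626) and a glutamine synthetase (OptiV1C13442) fell 6.43-fold, 5.4-fold and 4.94-fold, and asparagine synthetase 4 (OptiV1C00703) had a log2 difference of -2.53 with 3 arrays of slice 10 above background. For 13 genes of plastid gene expression and division, 5 rose and 5 fell (adjusted p = 0.956): Golden2 (OptiV1C04188) and a sigma factor (OptiV1S19116) fell 6.87-fold and 2.81-fold, and a Tic20-like protein (OptiV1C02619) and SIG2A (OptiV1S29216) rose 5.24-fold and 2.67-fold. That list also held mitochondrial chaperonin 60 (OptiV1C04461, log2 difference -0.14) and a sigB regulation protein (OptiV1C15143, -1.08), which are not of plastid gene expression by their names.

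Stress, phloem and reference genes likewise went both ways at the base. For 90 heat shock and chaperone genes, 23 rose and 41 fell (median -0.31, or 0.65 when scaled to spike-in transcripts, adjusted p = 0.507), and 2 of the hsp20 family (OptiV1S20123, OptiV1S22317) were at least 161-fold and 63.9-fold higher. The dnaJ genes OptiV1C12806 and OptiV1S19837 rose 20.2-fold and fell 11.1-fold. For 67 defence genes, 30 rose and 23 fell (adjusted p = 0.119). Beta-1,3-glucanases (OptiV1C16196, OptiV1C00956) were at least 90.9-fold and 24.3-fold higher, pathogenesis-related protein 2 (OptiV1S28031) rose 88.7-fold and pathogenesis related protein-5 (OptiV1S19844) fell 55.6-fold. For 8 phloem genes, 4 rose and 3 fell (adjusted p = 0.808). A callose synthase subunit (OptiV1C03097) rose 2.28-fold, a phloem lectin (OptiV1S27426) had a log2 difference of -1.69 with 1 array of slice 10 above background, and a callose synthase (OptiV1C16894) was at least 1.78-fold lower. Another callose synthase subunit (OptiV1C11592) fell by 0.94 on the log2 scale but had 0.01 when scaled to spike-in transcripts. For 60 reference genes, 20 rose and 27 fell (adjusted p = 0.872). Tubulin alpha-3 (OptiV1C09714) and a polyubiquitin (OptiV1C13256) rose 13.7-fold and 10.7-fold, an alpha-tubulin (OptiV1S28563) had a log2 difference of 4.36 with 1 array of slice 1 above background, and tubulin alpha-6 (OptiV1C04499) fell 8.55-fold.

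The counts of these 9 lists were the same when adjusted over the list alone. Median, mean and test differed in sign for phloem, senescence, nitrogen assimilation, plastid gene expression and reference genes, whose means were -0.14, 0.50, 0.14, -0.09 and 0.31. The lists of stomata and of benzoxazinoids had 2 measured genes each and were not tested. The potassium channel KZM2 (OptiV1S19669) had a log2 difference of -3.16 with 3 arrays of slice 10 above background, a stomatin-like protein (OptiV1C12525), which is not a stomatal protein, had 0.13 (adjusted p = 0.464), indole-3-glycerol phosphate lyase1 (OptiV1C11788) rose 1.89-fold and benzoxazinless1 (OptiV1C10776) had 0.35 (adjusted p = 0.178).

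Some of these single-gene calls for slice 10 against 1 were lost under other settings. With normexp, log2 differences that no longer passed were 0.43 (OptiV1C01051) and -0.98 (OptiV1C00084) for carbonic anhydrases, 0.21 for the housekeeping carboxylase (OptiV1C10576), 0.45 for sucrose transporter 2 (OptiV1S28476) and -0.43 for the bisphosphatase (OptiV1C00797). They were 0.56 for replication origin activator 2 (OptiV1S33750), -0.80 for cyclin1 (OptiV1C05468), 0.07 for MAD2 (OptiV1C10408), -1.35 for the cinnamoyl CoA reductase-like gene (OptiV1C04740), -0.81 for the phloem lectin (OptiV1S27426) and -0.76 for a callose synthase (OptiV1C16894). They were 1.08 for asparagine synthetase 2 (OptiV1C06380), 0.29 for OptiV1N37559, 1.02 for liguleless4 (OptiV1C15422), 0.99 for a glucosyltransferase (OptiV1S31770), 1.38 for a beta-1,3-glucanase (OptiV1C00956) and 1.10 for an alpha-tubulin (OptiV1S28563). Beside the genes with a spike-in value above, that scaling lost the calls of the sucrose phosphate synthase OptiV1C14880 (-0.48), the arabinogalactan protein OptiV1C13799 (-0.28), the phloem lectin (OptiV1S27426, -0.73) and the callose synthase OptiV1C16894 (-0.63). With scan day as a term, calls were lost for coproporphyrinogen III oxidase (OptiV1C15980, 1.14), magnesium chelatase (OptiV1C13645, 0.73), the bisphosphatase (OptiV1C00797, -1.04), MAD2 (OptiV1C10408, 2.18) and the phloem lectin (OptiV1S27426, -1.52). The same held for a callose synthase subunit (OptiV1C11592, -0.77), a glucosyltransferase (OptiV1S31770, 1.66), pathogenesis related protein-5 (OptiV1S19844, -2.59) and indole-3-glycerol phosphate lyase1 (OptiV1C11788, 0.58).

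Slice 10 against slice 5 compared the base with the middle of the leaf. Genes of photosystems, of the Calvin cycle and of starch were lower at the base and ribosomal genes higher. The lists of the C4 cycle (6 rose and 9 fell, adjusted p = 0.159), chlorophyll synthesis (4 and 2, adjusted p = 0.859) and photorespiration (1 and 4, adjusted p = 0.367) did not pass. The C4 list did pass with normexp (median -1.01, adjusted p = 0.0289) and with spike-in scaling (-0.31, adjusted p = 0.0257). Spike-in scaling also gained sucrose synthesis (adjusted p = 0.037) and the cell cycle (adjusted p = 0.0487), and the array median gained defence genes (adjusted p = 0.0333). Sucrose phosphate synthase1 (OptiV1C10670) was 357-fold lower (log2 difference -8.48, SE 0.203), 3 PTR2 transporters (OptiV1C08933, OptiV1S18541, OptiV1S22702) 300-fold, 288-fold and 122-fold lower, and bundle sheath cell specific protein 1 (OptiV1C04996) 199-fold. The 5 largest rises were again lipid binding proteins (OptiV1S31825, 1020-fold, log2 difference 10, SE 0.365, and OptiV1S19459, 854-fold), the membrane transporter OptiV1C11461 (567-fold), ascorbate oxidase (OptiV1C02069, 472-fold) and OptiV1C03933 (352-fold). Of 52 photosystem and light harvesting genes, 49 fell and 1 rose, the oxygen-evolving enhancer OptiV1S21007, also when adjusted over the list alone, with a median of -1.27 (adjusted p = 3.16e-11; adjusted p = 0.144 with an estimated correlation). Much of this fall was shared by genes of the same brightness, as 1000 random lists of them had medians of -1.22 to -0.61, with a median of -0.92.

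Of 12 Calvin cycle genes, 10 fell and 0 rose (median -1.65, adjusted p = 0.000626; adjusted p = 0.112 with an estimated correlation), and of 30 starch genes 21 fell and 6 rose (median -1.55, adjusted p = 0.000626; adjusted p = 0.144 with an estimated correlation). Of 10 clock genes, 9 fell and 1 rose (median -1.54, adjusted p = 0.0211; adjusted p = 0.112 with an estimated correlation), the latter an Adagio-like gene (OptiV1C07036, log2 difference 0.30) named after its values were seen. Of 110 cytosolic ribosomal protein genes, 102 rose and 4 fell (5 adjusted over the list alone), with a median of 1.91 (adjusted p = 2.97e-24; adjusted p = 0.112 with an estimated correlation). Of 35 secondary wall genes, 23 rose and 7 fell (median 1.51, adjusted p = 0.000253; adjusted p = 0.112 with an estimated correlation). Plastid ribosomal protein genes (31 rose and 6 fell of 42, median 0.56, adjusted p = 0.000841; adjusted p = 0.144 with an estimated correlation) and wall expansion genes (27 rose and 11 fell of 48, median 0.70, adjusted p = 0.0147; adjusted p = 0.328 with an estimated correlation) passed too, but not with scan day as a term (medians 0.10 and 0.52, adjusted p = 0.987 and 0.108). Among probes above background on all arrays, the calls of wall expansion (median 0.21, adjusted p = 0.301) and the clock (adjusted p = 0.0683) were lost, the latter also with normexp and bright backgrounds set to the median (adjusted p = 0.176). Of the random lists of equal brightness, 8 were as low as the Calvin cycle list (median of the lists -0.91) and 14 as low as the clock list (-0.41). Apart from the cytosolic ribosomal list, the counts of these lists were the same when adjusted over the list alone.

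In all, 23193 probes differed between slices 10 and 5, with 10273 higher and 12920 lower at the base, and the 10 genes named here differed the same way in slice 10 against 7. Their adjusted p ran from 2.95e-29 (OptiV1S19459) to 4.73e-22 (OptiV1S31825). With scan day as a term, 19525 probes had a linear trend over slices 5 to 10. Scaled to spike-in transcripts, the median of all probes was 0.768 in place of -0.145, with 18020 probes higher and 3606 lower.

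Slice 5 against slice 1 compared the middle with the tip. Genes of photosystems and chlorophyll synthesis were higher in the middle, and the largest falls from the tip included an alternative oxidase and a pathogenesis-related protein. The list of defence genes did not pass (22 rose and 20 fell of 67, median 0.10, adjusted p = 0.885). O-succinylhomoserine sulfhydrylase (OptiV1S32087) was 76-fold lower in the middle (log2 difference -6.25, SE 0.521) but had its highest mean in slice 9. Lower in the middle were also carbonyl reductase 1 (OptiV1S24191) 57.9-fold, a pathogenesis-related protein of class I (OptiV1S27128) 48.5-fold, alternative oxidase AOX3 (OptiV1C10427), a mitochondrial terminal oxidase, 46.5-fold (log2 difference -5.54, SE 0.254) and wall-associated kinase 4 (OptiV1S33511) 41.6-fold. Pollen-specific protein SF3 (OptiV1C17579) was 27.4-fold higher (log2 difference 4.78, SE 0.211), an acyltransferase (OptiV1C10534) 14.5-fold, a transferase family protein (OptiV1C00746) 14.4-fold, a beta-glucosidase (OptiV1C00609) 13.7-fold and terpene synthase 8 (OptiV1C02720) 12-fold. Of 52 photosystem genes, 49 rose and 0 fell (50 and 0 adjusted over the list alone), with a median of 0.88 (adjusted p = 2.28e-17; adjusted p = 0.104 with an estimated correlation). Random lists of equal brightness rose too, with medians of 0.24 to 0.70 and a median of 0.50.

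Chlorophyll synthesis genes (7 rose and 0 fell of 8, or 8 and 0 adjusted over the list alone, median 1.07, adjusted p = 0.000124) and plastid ribosomal protein genes (27 rose and 8 fell of 42, or 28 and 8 adjusted over the list alone, median 0.97, adjusted p = 1.6e-07) rose from tip to middle. They were the 2 lists that held in any comparison with an estimated correlation (adjusted p = 0.0448 for both). Of 12 Calvin cycle genes, 10 rose and 0 fell (median 0.75, adjusted p = 0.000852; adjusted p = 0.149 with an estimated correlation), and of 30 starch genes 18 rose and 3 fell (median 0.45, adjusted p = 0.000852; adjusted p = 0.15 with an estimated correlation). Wall expansion genes (24 rose and 5 fell of 48, median 0.73, adjusted p = 0.000124; adjusted p = 0.149 with an estimated correlation) and secondary wall genes (17 rose and 8 fell of 35, median 0.55, adjusted p = 0.0136; adjusted p = 0.168 with an estimated correlation) rose as well. Of 14 cuticle genes, 10 rose and 2 fell (median 0.81, adjusted p = 0.00355; adjusted p = 0.149 with an estimated correlation). For these 5 lists the counts were the same when adjusted over the list alone. Of 1000 random lists of equal brightness, 52 were as high as the Calvin cycle list (median of the lists 0.50) and 5 as high as the starch list (0.10). The Calvin cycle call was lost with quantile normalization (median 0.31, adjusted p = 0.15). The starch call was lost with normexp (median 0.54, adjusted p = 0.0557, or 0.51 and 0.0546 with bright backgrounds set to the median). The secondary wall call was lost with the latter setting (median 0.61, adjusted p = 0.0546). Of 110 cytosolic ribosomal protein genes, 85 fell and 4 rose (88 and 4 adjusted over the list alone), with a median of -0.70 (adjusted p = 2.67e-17; adjusted p = 0.149 with an estimated correlation).

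In all, 15759 probes differed between slices 5 and 1, with 8367 higher and 7392 lower in the middle. The adjusted p of the 10 named genes ran from 5.65e-20 (OptiV1C00746) to 6.84e-11 (OptiV1S27128). All 10 differed the same way in slice 2 against 1, within the first scan day, and 7 in slice 6 against 3, within the second. With scan day as a term, 6871 probes had a linear trend over slices 1 to 5, 6215 of them among the 15759 with the same sign. The calls of OptiV1S32087, OptiV1S24191 and AOX3 (OptiV1C10427) were lost, with log2 values of -3.91, -3.94 and -3.5 (adjusted p = 0.103, 0.0851 and 0.0792). With scaling to probes above background on all arrays, 6964 probes were higher and 8834 lower in the middle, and with normexp and bright backgrounds set to the median 16271 were higher and 5297 lower.

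**Figure D2:**
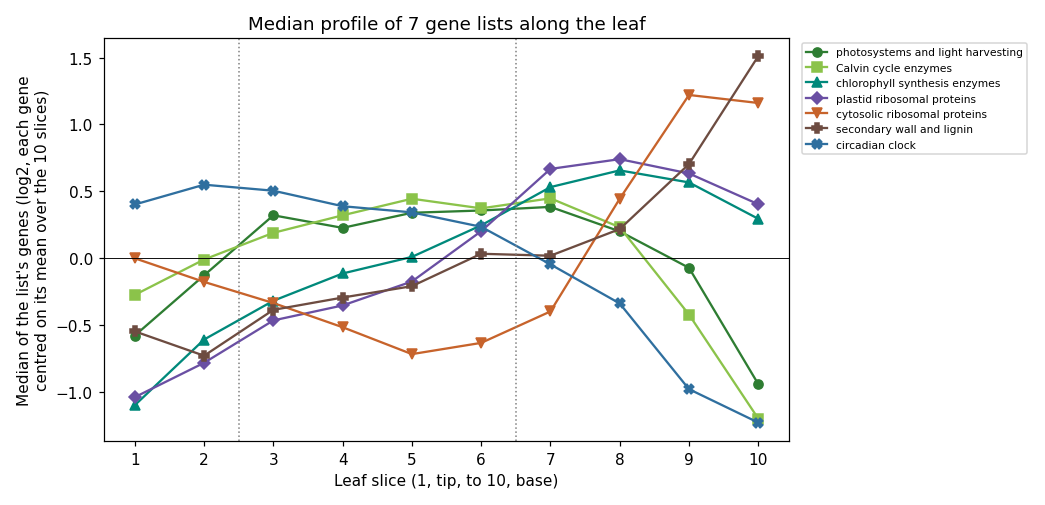
Median profile of 7 gene lists by leaf slice, as log2 signal with each gene centred on its mean over the 10 slices. Each point is the median of a list's genes, and dotted lines part slices of different scan days. Cytosolic ribosomal protein genes were lowest in slice 5 with -0.72 and highest in slice 9 with 1.22. Photosystem genes ran from 0.38 in slice 7 to -0.94 in slice 10. When arrays are scaled to spike-in transcripts, their last step is upward, as is the median of all genes.

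The change from middle to base was then tested against the change from tip to middle. After scaling, photosystem, Calvin cycle and starch genes were higher in slice 5 than in slices 1 and 10, and cytosolic ribosomal genes lower. The difference between the 2 changes had a median of -2.23 for photosystem genes (adjusted p = 1e-17), -2.45 for Calvin cycle genes (adjusted p = 5.95e-05) and -2.25 for starch genes (adjusted p = 3.06e-06). It was 2.54 for cytosolic ribosomal genes (adjusted p = 5.42e-29), and for each of these 4 lists the adjusted p was 0.0619 with an estimated correlation. Secondary wall genes (median 0.97, adjusted p = 0.0415; adjusted p = 0.247 with an estimated correlation) and genes of the cell cycle (median 0.66, adjusted p = 0.0415; adjusted p = 0.0619 with an estimated correlation) also passed. Part of this was shared by genes of the same brightness: random lists had a median difference of -1.55 for photosystems (0 of 1000 as low as the list, the lowest at -1.89), -1.61 for the Calvin cycle (7 as low) and -0.33 for starch (0 as low). For single probes, 20160 differed, 9101 higher and 11059 lower, and scaled to spike-in transcripts 12871 were higher and 3438 lower, with a median of all probes of 0.743 in place of -0.131. Of the tested probes, 4168 (13.1%) were higher in slice 5 than in slices 1 and 10 with both changes called, and 3372 (10.6%) lower.

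Slice 10 against slice 9 compared tissue inside the sheath with the youngest slice outside it, both of the same scan day. Inside the sheath, secondary wall genes were higher. Photosystem genes were lower relative to all genes, by less with normexp and quantile normalization. They rose along with all genes when scaled to spike-in transcripts. A proline-rich protein (OptiV1C04539) was 34.2-fold higher in slice 10 (log2 difference 5.1, SE 0.438), a lipid binding protein (OptiV1S27761) 20.4-fold, proline-rich protein APG (OptiV1C00096) 17.8-fold, blue copper protein (OptiV1S20506) 16.6-fold and a lipid transfer protein (OptiV1C04981) 16.3-fold. Sucrose phosphate synthase1 (OptiV1C10670) was 13.6-fold lower (log2 difference -3.77, SE 0.203), Bowman-Birk trypsin inhibitors (OptiV1C06993, OptiV1C15772) 11.9-fold and 8.52-fold (the latter with an SD of 2.47 in slice 9), a PTR2 transporter (OptiV1C08933) 9.03-fold and cytokinin-O-glucosyltransferase 1 (OptiV1S30934) 8.81-fold. Of 52 photosystem genes, 48 fell and 0 rose (49 and 0 adjusted over the list alone), with a median of -0.85, or 1.02 when scaled to spike-in transcripts (adjusted p = 8.57e-20; adjusted p = 0.177 with an estimated correlation). With spike-in scaling the median of all genes rose by 1.78, and camera still called the list lower than other genes (adjusted p = 0.0103).

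Of 12 Calvin cycle genes, 9 fell and 1 rose in slice 10, a ribulose-phosphate 3-epimerase (OptiV1C01666, log2 difference 0.38) named after its values were seen, with a median of -0.84, or 1.03 when scaled to spike-in transcripts (adjusted p = 0.000463; adjusted p = 0.177 with an estimated correlation). Of 30 starch genes, 16 fell and 2 rose, with a median of -0.41, or 1.45 when scaled to spike-in transcripts (adjusted p = 0.000475; adjusted p = 0.186 with an estimated correlation). Of 42 plastid ribosomal protein genes, 16 fell and 0 rose, with a median of -0.22, or 1.65 when scaled to spike-in transcripts (adjusted p = 0.0212; adjusted p = 0.435 with an estimated correlation). Of 1000 random lists of genes with the same brightness, 911 had a median as low as theirs, against 25 for the Calvin cycle (median of the lists -0.55) and 5 for starch (-0.12). Of 35 secondary wall genes, 18 rose and 6 fell (18 and 7 adjusted over the list alone), with a median of 0.36 (adjusted p = 0.00301; adjusted p = 0.179 with an estimated correlation). The Calvin, starch and plastid ribosomal counts were the same when adjusted over the list alone. Spike-in scaling lost these 3 calls (adjusted p = 0.0619, 0.0769 and 0.483). Normexp with bright backgrounds set to the median lost the Calvin call (adjusted p = 0.0505). The plastid ribosomal call was also lost with both normexp settings (adjusted p = 0.205 and 0.42), quantile normalization (median -0.07, adjusted p = 0.93) and probes above background on all arrays (adjusted p = 0.0562). Quantile normalization gained cytosolic ribosomal (adjusted p = 0.0281) and cytokinin genes (adjusted p = 0.0341). Spike-in scaling gained nitrogen assimilation, cytokinin, defence and reference genes (adjusted p = 0.0137, 0.00322, 0.00115 and 0.0103).

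In all, 13160 probes differed between slices 10 and 9, with 5734 higher and 7426 lower in slice 10. The adjusted p of the 10 named genes ran from 3.17e-20 (OptiV1C04981, OptiV1S30934) to 0.00114 (OptiV1C15772). Scaled to spike-in transcripts, the median of all probes was 1.8 in place of -0.0701, and 30479 probes were higher and 80 lower. With that scaling the call of OptiV1C15772 was lost (log2 difference -1.22, adjusted p = 0.112). Its log2 difference of -3.09 became -2.35, -3.91, -3.69 and -2.41 without slice 9 replicates 1, 2, 3 and 4.

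**Figure D3:**
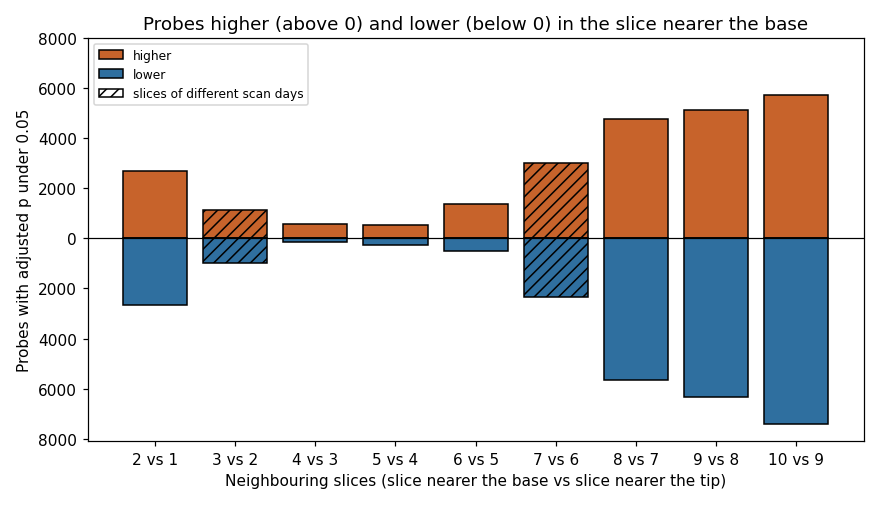
Number of probes with adjusted p under 0.05 between neighbouring slices, as probes higher (above 0) and lower (below 0) in the slice nearer the base. Hatched bars are pairs scanned on different days. The fewest probes differed between slices 4 and 3 (707) and the most between slices 10 and 9 (13160).

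Between neighbouring slices, named genes changed in stretches of the leaf. Between slices 2 and 1, carbonyl reductase 1 (OptiV1S24191) and a transposon protein (OptiV1C13995) were 19.4-fold and 18.7-fold lower, and the beta-glucosidase OptiV1C00609 and terpene synthase 8 (OptiV1C02720) 3-fold and 2.64-fold higher. Between slices 3 and 2, SMC1 (OptiV1C17316) and cytochrome b6 (petB, OptiV1C16387) were 4.18-fold and 3.52-fold higher, and a leucine rich repeat protein (OptiV1S23249) and transparent testa 12 (OptiV1C09983) 3.21-fold and 3.2-fold lower. The means of SMC1 and cytochrome b6 fell within the second scan day, from 1.6 and 6.33 in slice 3 to -0.38 and 5.58 in slice 6. They rose again across the next change of scan day, to 0.99 and 6.6 in slice 7, so scan day and position cannot be told apart for these rises. The acyltransferase OptiV1C10534 (2.62-fold) and SF3 (OptiV1C17579, 2.36-fold) were higher in slice 4 than in slice 3. Leucoanthocyanidin dioxygenase (OptiV1C05333), an enzyme of anthocyanin synthesis, was 1.89-fold lower and a clathrin assembly protein (OptiV1C17285) 1.83-fold. Beta-D-xylosidase (OptiV1C13267) was higher by 8.45-fold in slice 5 against 4, 6.93-fold in slice 6 against 5 and 4.41-fold in slice 7 against 6, and the dioxygenase (OptiV1C05333) was 2.39-fold and then 2.68-fold lower in the first pair of these steps.

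O-methyltransferase ZRP4 (OptiV1C03099) was 4.67-fold higher and a single-stranded DNA-binding protein (OptiV1S18528) 2.62-fold lower in slice 5 than in slice 4. The beta-amylase OptiV1C02764 was 8.56-fold higher and a plant-specific domain protein (OptiV1C03642) 2.54-fold lower in slice 6 than in slice 5. In slice 7 against 6, a xyloglucan endotransglucosylase (OptiV1C11915) was 8.4-fold higher, and a late embryogenesis abundant protein (OptiV1C07164) and isoflavone reductase IRL (OptiV1C01000) were 3.47-fold and 3.21-fold lower. In slice 8 against 7, an early nodulin-like protein (OptiV1C04068) and a peroxisomal ascorbate peroxidase (OptiV1C08203) were 15.8-fold and 14.6-fold higher, and IRL (OptiV1C01000) and PL3K2 (OptiV1S25013) 9.8-fold and 6.26-fold lower. In slice 9 against 8, wall protein gp1 (OptiV1S20294) and the lipid binding protein OptiV1S19459 were 138-fold and 68.5-fold higher, and IRL (OptiV1C01000) and the dikinase (OptiV1C17314) 17.1-fold and 12.7-fold lower.

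From tip to base, the neighbouring pairs differed in 5368 probes (2706 higher, 2662 lower in the slice nearer the base), 2125 (1133, 992), 707 (554, 153), 798 (543, 255), 1853 (1361, 492), 5352 (3006, 2346), 10419 (4766, 5653), 11471 (5125, 6346) and 13160. Of these pairs, 3 against 2 and 7 against 6 crossed scan days. Within the second scan day, 6098 probes differed between slices 5 and 3 and 11468 between 6 and 3. Scaling to the array median gave 1150 higher and 546 lower for slice 3 against 2, 848 and 612 for 6 against 5, and 2189 and 3100 for 7 against 6. Scaling to probes above background on all arrays gave 2171 higher and 3005 lower for slice 2 against 1, and 954 and 1303 for 3 against 2. Scaled to spike-in transcripts, the share of differing probes that were higher was 0.468% for slice 2 against 1, 66.7% for 3 against 2, 23796 of 23801 for 4 against 3, 79.2% for 5 against 4, 86.7% for 6 against 5, 4.38% for 7 against 6, 72.1% for 8 against 7 and 4.07% for 9 against 8. Fitted to the compared slices alone, 8 probes differed between slices 4 and 3 and 35 between 5 and 4, and no gene named for those 2 pairs passed, nor did the beta-amylase OptiV1C02764 for slice 6 against 5 (adjusted p = 0.0752), whose log2 difference of 3.1 was 3.72 without slice 5 replicate 4. With normexp, no named gene passed for slices 4 against 3 and 5 against 4, and calls were lost for OptiV1C02720 (slice 2 against 1), OptiV1S23249 and OptiV1C09983 (3 against 2), OptiV1C05333 and OptiV1C03642 (6 against 5), OptiV1C13267 (7 against 6) and OptiV1C08203 (8 against 7). Normexp with bright backgrounds set to the median lost OptiV1C10534 (4 against 3). Spike-in scaling lost OptiV1S23249 and OptiV1C09983 (3 against 2), OptiV1C05333 and OptiV1C17285 (4 against 3) and OptiV1C03642 (6 against 5). The call of transparent testa 12 (OptiV1C09983, adjusted p = 0.0327) was lost without any of 7 of its 8 arrays, with adjusted p up to 0.128 without slice 3 replicate 1. That of the dioxygenase OptiV1C05333 in slice 4 against 3 (adjusted p = 0.0392) was lost without any of 6 arrays, with adjusted p up to 0.119 without slice 4 replicate 1. In slice 10 against 1, that of the callose synthase OptiV1C16894 (adjusted p = 0.033) was lost without any of 5, with adjusted p up to 0.118 without slice 10 replicate 2.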

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

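The splits of the arrays and the tests of the 3 patterns weighed were chosen after the results they bear on were seen, except the test for dim probes above background on the first scan day.

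Along the leaf, 4 gene lists changed in opposite directions in its basal and distal parts, by a test of the difference (slice 10 minus 5 against slice 5 minus 1), though each of the 4 was lost with an estimated correlation (adjusted p = 0.0619), as were their calls in each part alone (adjusted p from 0.104 to 0.15). The median difference was -2.45 for the Calvin cycle, -2.23 for photosystems and light harvesting, -2.25 for starch and 2.54 for cytosolic ribosomal proteins. Much of the first pair was shared by genes of the same brightness, whose random lists had medians of -1.61 and -1.55. Single probes that differed in the same test numbered 20160, and of the 166 named genes 29 were called in opposite directions in the 2 parts, 20 of them with higher levels in slice 5. Of 100 random splits of the arrays, 1, the real one, gave as many probes, and the highest other gave 17903. A random sorting of the arrays can be excluded at this level, but slide cannot, since each slice had its own slide.

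The first pattern weighed is the fall of photosystem and light harvesting genes from slice 9 to slice 10 (median -0.847). Array scaling could account for part of it: against the median of all genes, the list lay at -0.758 as reported, at -0.567 with normexp and at -0.251 with quantile normalization. Spike-in scaling also gave -0.758, but it shifts all probes of an array alike and so cannot change this value. Compression of bright signals stays open as much of the fall, and whether it is the whole cause cannot be decided. Of 1000 random lists of genes with the same brightness, 0 were as low (-0.825 to -0.407, their median -0.619, pooled genes -0.413). The gap to the lowest was narrow, and the brightest matched gene (9.6) was dimmer than the list's brightest (9.97). Unscaled, the 75th percentile was 9.226 in slice 9 and 9.933 in slice 10. The highest percentile taken was 17.44 in both, so it fell after scaling, as compression would give. The last step was 2.45 times the largest fall of the 4 steps before it, and 2.24 to 3.13 times under other scalings. With spike-in scaling it was a rise of 1.02, below the median rise of 1.78 of all genes. Enclosure of slice 10 by the sheath, its age and its slide cannot be told apart, since slice 10 alone was inside the sheath and each slice had its own slide.

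The second pattern is that of 3102 probes at least 1 lower on the log2 scale in slice 5 than in slice 1, which were scanned on different days. Scan day as the whole cause is argued against: of 3000 probes chosen with 2 arrays of slice 1 left out, 92.5% were lower in slice 2 of the same day than in those arrays, against 42.5% of all tested probes. Part stays open, as the median step was -0.611 from slice 1 to 2 and -1.63 from slice 1 to 5, 45.1% were called between slices 1 and 2, and 50.2% passed with scan day as a term. More dim probes above background on the first day is argued against as the whole cause, since 55% of the pattern was well above background on all 8 arrays. That share was low, as 22147 of the 31830 tested probes were well above background on every array of the series. The pattern was thus richer in dim probes than the tested probes, and this explanation stays open for part of it. Tissue age at the tip, and any injury or drying there, remain as untested biological explanations. The slide of slice 1 cannot be told apart from these, since the arrays left out shared it with those used for choosing.

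The third pattern is the signal of the spike-in transcripts, which no comparison used as reported. In slice 10 it was 2.97 above the 75th percentile on the log2 scale (SD 0.529, n = 4), against 3.76 to 4.84 in the other slices, but this rests on replicates 1 to 3 (2.58 to 2.81), since replicate 4 at 3.75 lay above the lowest single array of the other slices (3.53). Less spike-in RNA on that slide and more labelled transcript per RNA loaded are both possible explanations. The unscaled spike-in signal of slice 10 was 12.9, within the 12.49 to 14.06 of the other slices, and its unscaled 75th percentile was 9.93 (SD 0.25, n = 4) against at most 9.52, in slice 1. These cannot be told apart, since the amounts of RNA and spike-in are not recorded, so whether total transcript differed in slice 10 stays open.

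Single arrays lay far from the other 3 of their slice in 1 of 30 groups of array measures and in 23 of 367 groups of named genes, where chance gives about 1 in 20. Slice 8 replicate 4 had a 75th percentile signal of 642, against 545 to 562. Among named genes in slice 10, replicate 1 had 2.72 for OptiV1C01965 (others 2.99 to 3.01), 1.39 for OptiV1C04499 (0.96 to 0.988), -5.63 for OptiV1S20128 (-7.2 to -6.99) and 4.85 for OptiV1S21029 (4.73 to 4.74). Replicate 3 had 1.08 for OptiV1C00971 (0.324 to 0.448) and 2.19 for OptiV1C02764 (1.75 to 1.78). Replicate 4 had -2.14 for OptiV1C12780 (-1.85 to -1.83), -1.43 for OptiV1C13442 (-1.82 to -1.77), 1.27 for OptiV1C13482 (0.913 to 0.929), 3.93 for OptiV1C15980 (4.4 to 4.42), -2.79 for OptiV1S18541 (-4.77 to -4.66), 3.66 for OptiV1S22576 (3.06 to 3.1), 2.38 for OptiV1S29106 (2.12 to 2.16) and 6.45 for OptiV1S30507 (5.95 to 6.01). In slice 1, replicate 3 had -3.15 for OptiV1C00703 (-2.08 to -1.89) and -4.98 for OptiV1C11915 (-4.72 to -4.7), and replicate 4 had -1.78 for OptiV1C12806 (-2.94 to -2.83), -5.16 for OptiV1C13256 (-4.45 to -4.32), -3.9 for OptiV1S20128 (-3.52 to -3.47) and 7.06 for OptiV1S21029 (6.77 to 6.78). The others were OptiV1C02720 in slice 5 replicate 4 (-0.0465, others -0.477 to -0.422), OptiV1C04981 in slice 9 replicate 2 (1.77, others 2.6 to 2.65) and OptiV1C13995 in slice 2 replicate 4 (-1.65, others -2.89 to -2.76).

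The arrays of the 2 slices of each pair were also split in all 35 ways. For every pair, 1 split, the real one, gave as many probes. A random sorting of the arrays can be excluded only at this level, 1 of 35 for each pair. That is the smallest share these splits can give, and it was not adjusted over the pairs. Slide cannot, since each slice had its own slide. The real and the highest other counts were 23168 and 13011 for slice 10 against 1, 23193 and 13729 for 10 against 5, 15759 and 4673 for 5 against 1, 5368 and 728 for 2 against 1, 2125 and 25 for 3 against 2, 707 and 123 for 4 against 3, and 798 and 135 for 5 against 4. They were 1853 and 629 for 6 against 5, 5352 and 384 for 7 against 6, 10419 and 4019 for 8 against 7, 11471 and 3733 for 9 against 8, and 13160 and 1905 for 10 against 9. Within scan days they were 21374 and 12233 for 10 against 7, 11468 and 2890 for 6 against 3, and 6098 and 1204 for 5 against 3. Over all 10 slices, 1 of 100 random splits, the real one, gave 29125 probes, and the highest other gave 5704. For the number of lists called, chance cannot be excluded: as many were called in 12 of 35 splits for slice 10 against 1 (8 lists, highest other 12), 13 for 10 against 5 (8, highest other 10), 7 for 5 against 1 (9, highest other 10) and 13 for 10 against 9 (5, highest other 7).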

How the results depend on the processing

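Scaling to spike-in transcripts, normexp with bright backgrounds set to the median, scan day as a term and the lists as first matched were chosen after the data were seen. Quantile normalization, scaling to the array median or to probes above background on all arrays, 1 probe per gene and the stricter filter kept every count they were run on within 1.5 times. Named differences kept their call and direction in 195 of 195 under those 3 scalings, array weights and the replicate block, in 162 with normexp, 194 with the median background, 178 with spike-in scaling, 186 with the compared slices alone and 141 of 153 with scan day as a term. In the authors' values 194 of 195 lay within 1 SD, and OptiV1C03099 (slice 5 against 4) had 0.952 in place of 2.22. Except where given, the cause of a change was not tested.

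Normexp gave 18878 probes among all slices, 13233 for slice 10 against 1, 14105 for 10 against 5, 4586 for 5 against 1, 535 for 2 against 1, 7 for 3 against 2, 0 for 4 against 3 and 0 for 5 against 4 (limma, 300 and 861 at unadjusted p under 0.05), 21 for 6 against 5, 72 for 7 against 6, 448 for 8 against 7, 4237 for 9 against 8, 3362 for 10 against 9 and 8602 for the basal against the distal change. Bright local backgrounds distorted that correction: on 11 arrays the corrected 1st percentile was over 2 times the offset, with a highest of 1110 against a median of 55.5. With median backgrounds, slice 2 against 1 gave 9924, 3 against 2 12521, 4 against 3 277, 5 against 4 466 and 8 against 7 15870, and 5 lists were called for 10 against 1 and 3 for 10 against 9. The share of probes higher was then 75.4% for 5 against 1 (53.1% as reported), 30.5% for 10 against 5 (44.3%), 28.3% for 10 against 9 (43.6%), 72.5% for 2 against 1 (50.4%), 90.6% for 3 against 2 (53.3%), 22.5% for 8 against 7 (45.7%) and 26.3% for the basal against the distal change (45.1%). Spike-in scaling gave 9795 for 5 against 1, 72 for 3 against 2, 23801 for 4 against 3, 24 for 5 against 4, 210 for 6 against 5, 9173 for 7 against 6, 3617 for 8 against 7, 19371 for 9 against 8 and 30559 for 10 against 9. A log2 difference of at least 1 left 13156 for 10 against 1, 12919 for 10 against 5, 5482 for 5 against 1, and from tip to base 1037, 376, 125, 139, 347, 1000, 2220, 2545 and 3384 for neighbours, fewer by construction. Scan day as a term gave 15070 for 10 against 1 and 6871 for 5 against 1. The compared slices alone gave 643 for 3 against 2, 8 for 4 against 3, 35 for 5 against 4, 526 for 6 against 5, 1643 for 7 against 6 and 6842 for 8 against 7, with fewer arrays for the spread. Array weights gave 8734 for 2 against 1 and 1451 for 5 against 4, and no filter on dim probes 3744 for 3 against 2. The replicate block gave 3233 for 3 against 2, 1150 for 4 against 3 and 1241 for 5 against 4. Of 180 same-numbered pairs, 137 correlated above 0.1 (mean 0.237, against -0.0772 for different numbers). Of the 40 arrays, 37 correlated best with their own number, which may be the pool or the position on the slide. Arrays of the same number thus shared variation. The reported tests did not pair the arrays and left this variation in their spread. With an estimated correlation, camera called 0 lists for 10 against 1, 0 for 10 against 5, 2 for 5 against 1 and 0 for 10 against 9, 2 of the 30 in all (5, 8, 8 and 5 at unadjusted p under 0.05). A scan-day block could not be fitted to slices of different days. Signal over background limits 13 named differences to a lower bound.

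Leaving out each array gave 28832 to 29403 probes among all slices, 22162 to 23043 for 10 against 1, 22302 to 22912 for 10 against 5, 14238 to 15341 for 5 against 1, 3480 (without slice 1 replicate 2) to 5896 for 2 against 1, 1036 to 2599 for 3 against 2, 389 to 700 for 4 against 3, 479 to 946 for 5 against 4, 1268 to 2117 for 6 against 5, 4128 to 5240 for 7 against 6, 8224 to 10553 for 8 against 7, 9264 to 11254 for 9 against 8, 11629 to 12676 for 10 against 9 and 18913 to 20175 for the basal against the distal change. It gave 7 to 11 lists for 10 against 1, 8 to 8 for 10 against 5, 9 to 10 for 5 against 1, 5 to 6 for 10 against 9, 29 to 33 in all, and 193 to 195 named differences. Changes above 1.5 times for 3 against 2 were 1211 and 1085 (without slice 2 replicates 2 and 3), 1036 and 1069 (slice 3 replicates 1 and 4), for 4 against 3 402 and 458 (slice 3 replicates 1 and 2) and 389 (slice 4 replicate 4), and for 5 against 4 490, 479 and 484 (slice 4 replicates 1, 2 and 3) and 484 (slice 5 replicate 4). Lists gained were photosystems (10 against 1) without slice 1 replicate 3, 6 replicate 1 or 10 replicate 4 (adjusted p = 0.0299, 0.0444, 0.0399), starch (10 against 1) in 11 cases (0.0413 to 0.05), leaf growth without slice 6 replicate 1 (0.0386), histones (5 against 1) without slice 1 replicate 2 or 5 replicate 3 (0.0385, 0.0473) and cytokinin (10 against 9) without slice 9 replicate 2 or 4 or 10 replicate 2 or 3 (0.0244, 0.0499, 0.0449, 0.0417).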

Other observations

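Along the whole leaf, 2747 of the tested probes (8.63%) rose from tip to middle and again from middle to base, and 2028 (6.37%) fell in both parts. A change was called in the basal part alone for 10878 probes (34.2%), in the distal part alone for 3444 (10.8%) and in neither for 5193 (16.3%). Among the genes named in the report, O-succinylhomoserine sulfhydrylase (OptiV1S32087) was high at both ends, with a mean of 2.29 in slice 1 and -3.96 in slice 5 and a log2 difference of 3.91 between slices 10 and 7.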
